A study of Populus ussuriensis with 18 samples.

How the data were processed

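RNA was measured in the basal ends of stem cuttings of in vitro plants of Populus ussuriensis, a poplar, at 9 time points from 0 h to 96 h after cutting. Each time point has 2 libraries, 18 in all. The labels do not say whether the 2 libraries of a time point came from separate plants or cultures, so the p-values measure only the spread between these libraries, which may be technical.

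The authors deposited 1 table per library with a transcript identifier and its FPKM, a read number scaled by transcript length and by the read total of the library, per the file headers. Bowtie2 version 2.2.3 and HISAT2 version 2.1.0 are named without a role, per the submitters' processing notes. The genome build, the annotation and the tool that computed the FPKM are not given in the sources used here. The column headed gene holds transcripts, and the identifiers are not paired with gene names in these files. No genome or annotation was used here, so positions, exons and gene functions are not given. The 34 gene lists fixed before the data were examined are written as gene names and descriptions, and none could be matched to an identifier. They, the set tests and the tissue markers were therefore not analysed here.

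Every table holds 65535 transcripts of 36385 loci and ends at line 65536, within the identifiers of prefix 17. Loci numbered beyond that point were not analysed here. Of the loci, 23353 have 1 listed transcript and 13032 have several.

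The read depth was recovered from the size of the steps between low FPKM values. An FPKM is a number of reads divided by a length and by the read total of its library. In the low values, from 0.015 to 0.07 FPKM, a read total was searched that gives whole-number lengths. A length from 60 to 17000 bp was then searched for each transcript that gives whole reads in every library after cutting. All 60197 transcripts above 0 in at least 6 of the 16 libraries after cutting gave such a length, against 0 of 2000 transcripts whose values were shifted at random. The totals are stated for single reads, an assumption that cannot change the ratios between libraries. They were 21914571 and 25026198 reads at 0 h and between 28460172 and 30651830 reads after cutting. A library of 30311719 reads resolves 0.0165 FPKM for a transcript of 2 kb. Counts from whole reads cover counting error only.

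The files of the 0 h libraries differ in kind from the others. After cutting, 100.0% of values above 0 were whole reads within 0.01 reads, and at 0 h 39.0% and 38.2% were. The 0 h libraries had no part in the search for lengths. With lengths of 2000 transcripts searched without 1 later time point, between 99.79% and 100.0% of values were whole in the 2 libraries left out, and between 37.11% and 40.8% at 0 h. At 0 h 83.7% and 83.4% of values were whole in loci with 1 listed transcript, and 15.78% and 15.004% in loci with several, among transcripts above 0 in at least 6 later libraries. In loci with several transcripts, the leading transcript held a median of 92.0% and 91.9% of the FPKM of its locus at 0 h, and between 47.9% and 49.5% after cutting. For this reason the FPKM of all listed transcripts of a locus were summed, and the locus was the unit of every test. That choice was made after the files were seen and before any count of changed loci was computed. Sums over transcripts do not remove a difference in how reads were placed on loci, so every comparison against 0 h is confounded with this difference between files. The comparisons between later time points do not use the 0 h levels, although the 0 h libraries enter the shared estimate of the spread.

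Loci with an FPKM of at least 1 in at least 2 libraries were tested, 26765 in all. Values were analysed as log2(FPKM + 1), so a fold change is on that scale and understates the change of low loci. A linear model with 1 mean per time point was fitted to all 18 libraries with limma 3.58.1 in R 4.3.3, with an intensity trend and robust variance estimation. The 19 pairwise comparisons and the F test over the 9 time points were two-sided. Loci with a Benjamini-Hochberg adjusted p below 0.05, adjusted within each comparison, were called changed. The time points were also joined into 3 phases before the data were examined. The early phase holds 0.5, 1 and 2 h with 6 libraries, the middle phase 6 and 12 h with 4 libraries, and the late phase 24, 48 and 96 h with 6 libraries. A count model was planned in case the files held counts, and was not used because they hold FPKM.

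The procedure was tested on simulated data for the comparison of 1 h with 0.5 h, over 25324 loci and 10 runs with 200 changed loci each. It recovered 31.4% of loci changed 1.5-fold, 89.2% at 2-fold, 99.2% at 4-fold and 98.6% at 8-fold. Of the calls, 5.52% were false. In the same runs, 12 h against 6 h, where no locus was changed, gave at most 1 call. Every simulated locus had the same spread between replicates beyond counting error, 10.4% of its mean, which measured loci need not share. The number of runs was raised to 10 after a first single run had given a larger share of false calls.

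By a rule fixed before the data were examined, at most 2 identifiers that rose and 2 that fell are named. They are those with the highest and lowest log2 fold change of the late phase against 0 h, among called loci with a mean of at least 10 FPKM in either and with every late library on the same side of both 0 h libraries. The rule asked for a gene name where names exist.

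The alternatives fixed before the data were examined were quantile normalization, no filter on low values, a pseudocount of 0.1, limma without trend and robust estimation, the replicate number as a block, fits of the compared libraries alone, a 2-fold minimum for the phases, and leaving out each library in turn. Alternatives chosen after seeing the data were transcripts as deposited, loci with 1 listed transcript, loci not listed at 0 in both 0 h libraries, limma-voom on the recovered reads, and fits without the 0 h libraries. Loci and reads were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.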

Results

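Transcript levels were followed at the cut end of poplar stem pieces over the first 96 h after cutting, the period in which such cuttings prepare adventitious roots, which are roots that form on tissue other than a root. Plants 2 weeks old, grown in vitro at 25 °C with 16 h of light and 8 h of dark on medium with 20 g/L sucrose, were cut, and the basal 0.5 cm was taken at 0, 0.5, 1, 2, 6, 12, 24, 48 and 96 h. Total RNA of 2 libraries per time point was sequenced. The libraries held 21914571 and 25026198 reads at 0 h and between 28460172 and 30651830 reads at later times.

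Libraries of one time point resembled each other more than libraries of any other pair. Pearson's r over the tested loci, which are not independent replicates, lay between 0.981 and 0.991 within a time point, between 0.883 and 0.977 for consecutive time points after cutting, between 0.705 and 0.941 for other time points after cutting, and between 0.717 and 0.878 for 0 h with a later time. No transcript above 0 had the same FPKM in both libraries of a time point.

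The number of loci that reached 1 FPKM did not move in one direction. It was 21134 and 21203 in the 0 h libraries and 23225 and 23236 at 0.5 h, a step that coincides with the difference between files described below. It was 22555 and 22758 at 1 h, 22489 and 22614 at 2 h, 22918 and 23133 at 6 h, between 23189 and 23496 from 12 h to 48 h, and 24227 and 24229 at 96 h. The 100 loci with most reads held 15.3% and 15.8% of the locus reads at 1 h and 12.4% and 12.6% at 12 h.

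The 0 h tables differed from all others in how the FPKM was spread over the transcripts of a locus. The leading transcript held a median of 92.0% and 91.9% of the locus at 0 h, against 47.9% to 49.5% in the 16 later libraries. Of the tested loci, 1789 (6.68%) were listed at 0 in both 0 h libraries, and between 100 and 319 in both libraries of a later time point. Among those 1789, 34 loci exceeded 20 FPKM in all 16 later libraries. Every comparison with 0 h below carries this difference.

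**Figure D1:**
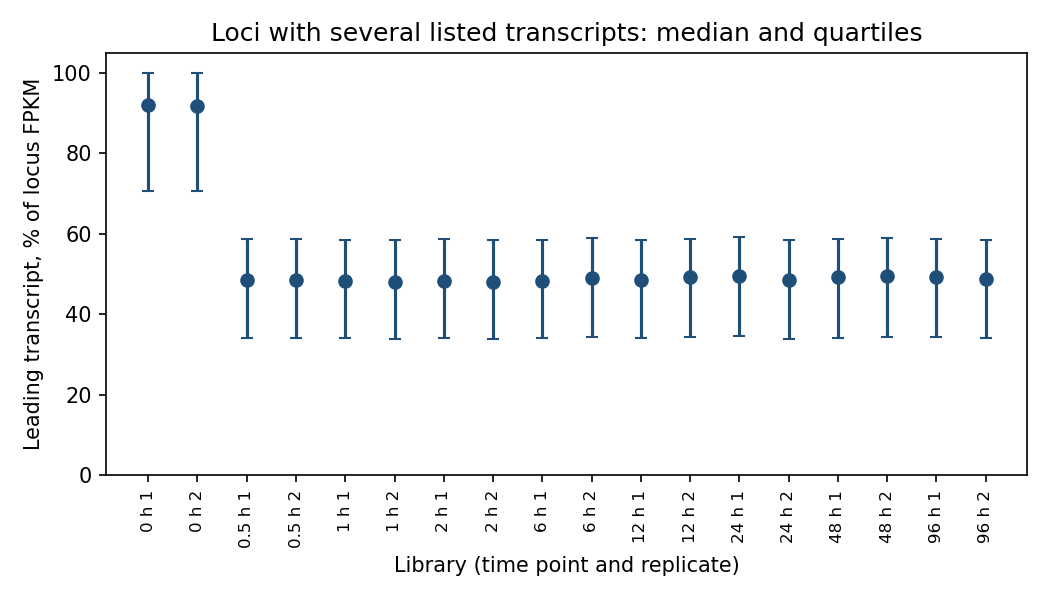
Share of the locus FPKM held by the leading transcript, in percent, over loci with several listed transcripts and at least 1 FPKM. Points are medians and bars the quartiles of each library; both 0 h libraries lie near 92.0% and the 16 later ones between 47.9% and 49.5%.

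Over the whole course, nearly all expressed loci changed. Of 26765 loci tested, 25654 (95.8%) differed among the 9 time points by limma's F test at a Benjamini-Hochberg adjusted p below 0.05. In a fit without the 0 h libraries, added after seeing the data, 24464 of 26626 loci (91.9%) differed among the 8 later time points. The highest and the lowest mean of 17265 of them were at least 2-fold apart, those of 5996 at least 4-fold and those of 931 at least 16-fold. The first principal component after cutting took 56.2% of the variance and separated 0.5 to 2 h from 6 to 96 h, and the second took 18.1%.

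**Figure D2:**
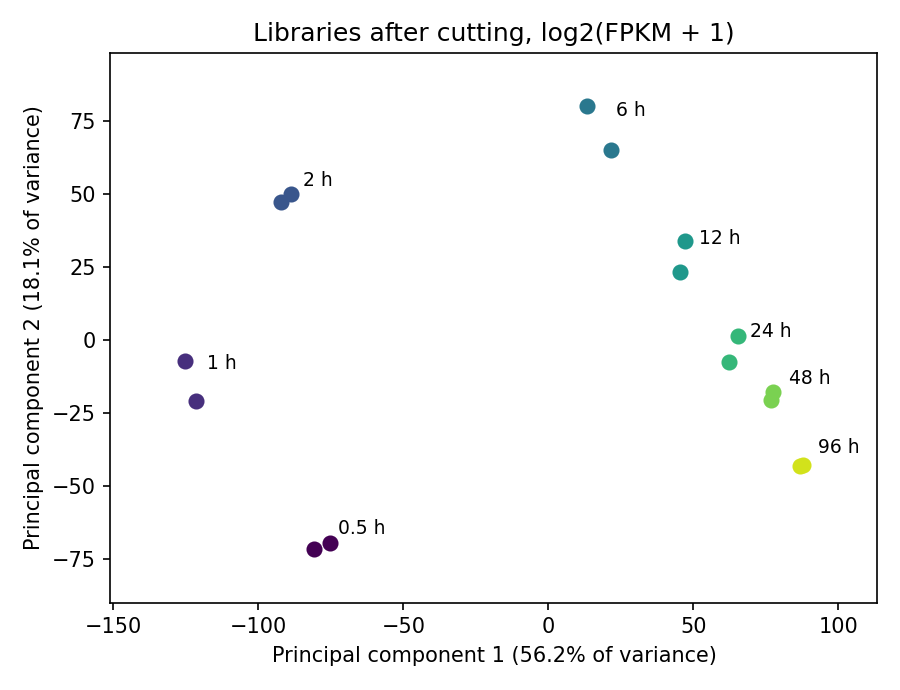
Principal components 1 and 2 of the 16 libraries after cutting, on log2(FPKM + 1), with the share of variance on each axis (56.2% and 18.1%). Each point is a library and each color a time point; the 2 libraries of a time point lie side by side, and the 0.5, 1 and 2 h libraries lie on the negative side of component 1.

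The comparisons with 0 h ask which loci left their level in stem ends taken at the time of cutting, and when. At 0.5 h, 6961 loci were higher and 6333 lower than at 0 h, 49.7% of those tested. The changes upwards were larger: 1357 loci were at least 4-fold higher and 132 at least 4-fold lower, and 227 were at least 16-fold higher against 3 lower. Of the 6961 higher loci, 1059 were listed at 0 in both 0 h libraries, and of the 227 at least 16-fold higher, 83 were. At 1 h, 7637 loci were higher and 10442 lower, and at 2 h, 8753 and 9666. From 6 h on higher loci were more numerous than lower ones: 9843 and 7452 at 6 h, 10026 and 6495 at 12 h, 9364 and 6270 at 24 h, 9872 and 6952 at 48 h, and 11360 and 6033 at 96 h.

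Which direction prevailed against 0 h depended, at every time point, on the scaling or on the loci counted. Quantile normalization lowered the share of higher loci among those changed from 52.4% to 37.3% at 0.5 h, from 56.9% to 45.3% at 6 h, from 60.7% to 44.7% at 12 h, from 59.9% to 44.4% at 24 h, from 58.7% to 45.0% at 48 h and from 65.3% to 46.8% at 96 h. At 1 h and 2 h lower loci prevailed under both scalings, with shares of higher loci of 42.2% and 40.3% at 1 h and 47.5% and 44.0% at 2 h, but not in other counts. Of loci changed at least 2-fold, 4485 were higher and 4083 lower at 1 h, and 4681 and 4332 at 2 h. Among loci with 1 listed transcript 5027 were higher and 4386 lower at 1 h, and 5386 and 4182 at 2 h. Among transcripts as deposited 25586 were higher and 15945 lower at 1 h, and 26323 and 15239 at 2 h. The last 2 sets carry the difference between files directly. The shares that follow are of transcripts with at least 1 FPKM in at least 4 later libraries. In loci with several, 38.5% and 37.8% of those not numbered first were at 0 at 0 h, against at most 0.224% later. In loci with 1 it was 12.1% and 12.0%, against at most 1.63%. Such transcripts tend to count as higher, so these 2 sets show no direction apart from the files. At 0.5 h, without the loci listed at 0 in both 0 h libraries, 5909 were higher and 6338 lower. The median log2 fold change of all loci went with quantile normalization from -0.012 to -0.181 at 0.5 h, from -0.131 to -0.179 at 1 h, from -0.027 to -0.116 at 2 h and from 0.088 to -0.087 at 6 h. It went from 0.143 to -0.093 at 12 h, from 0.105 to -0.096 at 24 h, from 0.119 to -0.085 at 48 h and from 0.225 to -0.063 at 96 h. Changes of 4-fold and more are far larger than these shifts, but still carry the difference between files.

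By phase, 8594 loci were higher and 9968 lower in the early phase than at 0 h, 10641 and 7434 in the middle phase, and 11422 and 7012 in the late phase. At least 4-fold changes were found upwards in 1540 loci and downwards in 520 in the early phase, 1480 and 596 in the middle phase, and 1407 and 489 in the late phase. With quantile normalization the share of higher loci among those changed was 40.65% in place of 46.3% in the early phase, 44.8% in place of 58.9% in the middle phase, and 45.7% in place of 62.0% in the late phase, and the median log2 fold change of all loci went from -0.051 to -0.150, from 0.121 to -0.090 and from 0.160 to -0.066. In the early phase higher loci prevailed among loci with 1 listed transcript, with 5601 higher and 4240 lower, among transcripts as deposited, with 27404 and 15765, and with a minimum of 2-fold, with 4092 and 2917. With that minimum the changed loci numbered 7009, 7204 and 6838 in the 3 phases. The early-phase counts of loci with 1 listed transcript and of transcripts as deposited carry the transcripts listed at 0 at 0 h.

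The loci that stood out most in the late phase followed 4 different courses. Potri.005G190100 had 2.70 ± 2.98 FPKM at 0 h, 121.5 ± 40 at 0.5 h, 371.1 ± 41.3 at 6 h, 1443 ± 198 at 12 h and 1746 ± 616 at 48 h (SD, n = 2 each). Its log2 fold change in the late phase was 8.80 (SE 0.36, limma adjusted p by Benjamini-Hochberg 5.25e-10). It was higher than both 0 h libraries in all 6 late libraries, as the rule for naming loci required. That rule also asked for a call and an extreme fold change in this comparison. The late-phase p-values of the 4 named loci are therefore no separate evidence. The size of the late-phase change of Potri.005G190100 rests on the low 0 h values of 4.80 and 0.587 FPKM: it was 9.74 without 0 h replicate 1 and 7.87 without 0 h replicate 2. It was 9.53 with a pseudocount of 0.1 and 9.70 with limma-voom on recovered reads. Independently of 0 h the locus rose from 2 h to 6 h by 1.83 on the log2 scale and from 6 h to 12 h by 1.95 (limma, Benjamini-Hochberg adjusted p 0.00408 and 0.0075).

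Potri.007G026100, with 1 transcript of 162 bp, was listed at 0 in both 0 h libraries, so no fold is given. It held 484.5 ± 20.7 FPKM at 0.5 h and 510.6 ± 10.5 at 48 h (SD, n = 2 each), from 1848 to 2916 reads per later library. Of the consecutive comparisons, only 96 h against 48 h was called for it, with a log2 fold change of -0.36 (limma, Benjamini-Hochberg adjusted p 0.0369). It shares the property described above of loci at 0 in the 0 h tables and at a high level in all later ones.

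Potri.004G168600, with 9 listed transcripts, fell by 6.62 on the log2 scale in the late phase (SE 0.29, limma adjusted p by Benjamini-Hochberg 5.15e-10). It held 393.9 ± 45.5 FPKM at 0 h and 548.1 ± 31.4 at 0.5 h, then 156.8 ± 43.2 at 1 h, 23.1 ± 3.55 at 6 h and 1.52 ± 0.285 at 96 h (SD, n = 2 each). Potri.003G207000 fell by 5.53 (SE 0.27, limma adjusted p by Benjamini-Hochberg 3.05e-10), from 116.7 ± 26.4 FPKM at 0 h to 33.8 ± 5.33 at 0.5 h and 1.81 ± 1.03 at 1 h. It was at 6.85 ± 1.46 FPKM at 24 h and back at 0.535 ± 0.0889 at 48 h, a drop that passed the test (limma, Benjamini-Hochberg adjusted p 0.00064). The late-phase log2 fold change of Potri.003G207000 was -6.55 with a pseudocount of 0.1 and -6.74 with limma-voom on recovered reads. Both loci were below both 0 h libraries in all 6 late libraries, as the rule for naming loci required.

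**Figure D3:**
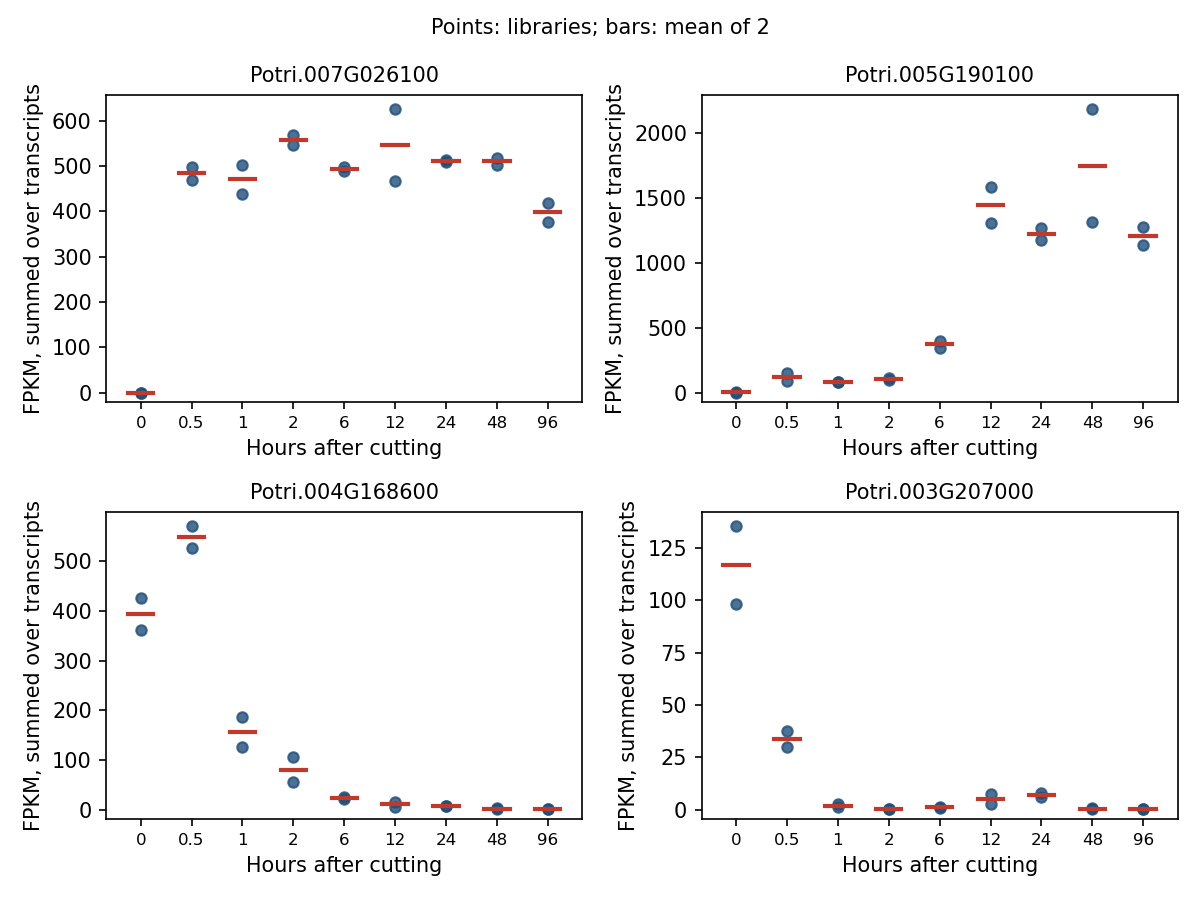
FPKM, summed over the transcripts of a locus, of the 4 named loci against hours after cutting, with the time points evenly spaced. Points are libraries and red bars the mean of the 2; Potri.007G026100 is listed at 0 only at 0 h, and Potri.004G168600 fell from 548.1 FPKM at 0.5 h to 1.52 at 96 h.

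The comparisons of consecutive time points ask in which interval the transcriptome moved, and do not use the 0 h levels. From 0.5 h to 1 h, 3710 loci rose and 8118 fell, of which 1297 and 1787 by at least 2-fold. Among loci changed at least 4-fold the direction turned, with 277 rising and 148 falling. From 1 h to 2 h, 5572 rose and 4169 fell, but of those changed at least 2-fold 1045 rose and 1222 fell. Between 2 h and 6 h the most loci changed, 9155 upwards and 4890 downwards. Of these, 2625 and 1954 changed by at least 2-fold, 423 and 517 by at least 4-fold and 27 and 69 by at least 16-fold. The counts then dropped to 3831 and 2571 from 6 h to 12 h, of which 56 and 76 by at least 4-fold. They were 2355 and 2836 from 12 h to 24 h, and 644 and 712 from 24 h to 48 h. From 48 h to 96 h they rose again, to 4999 loci higher and 2618 lower, with 1252 and 653 at least 2-fold. The intervals differ in length, so the counts are not rates. The plants were kept on 16 h of light and 8 h of dark, and the labels do not give the time of day. Only 24, 48 and 96 h are whole days after 0 h, and no uncut control of the later times is among the libraries. Changes with the time of day therefore cannot be told apart from a response to cutting, here, against 0 h or between phases.

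Quantile normalization changed the share of rising loci among those changed from 31.4% to 47.3% for 0.5 h to 1 h, from 65.2% to 54.7% for 2 h to 6 h and from 65.6% to 52.9% for 48 h to 96 h. The median log2 fold change of all loci went from -0.165 to -0.039, from 0.149 to 0.037 and from 0.074 to -0.021 in these. The share went from 57.2% to 52.3% for 1 h to 2 h, from 59.8% to 51.4% for 6 h to 12 h and from 47.5% to 47.8% for 24 h to 48 h. For 12 h to 24 h it went from 45.4% to 50.6%, which turned the prevailing direction. It turned there among transcripts as deposited too, with 3680 rising and 3631 falling, and without 12 h replicate 2, with 1783 and 1778. The clearest turn there was among loci changed at least 2-fold, with 626 rising and 356 falling. For 24 h to 48 h it turned with no filter on low values (634 rising, 623 falling), among loci with 1 listed transcript (414 and 410), without 24 h replicate 2 (323 and 320), and without 48 h replicate 1 (334 and 316) or 2 (385 and 378). It also turned among loci changed at least 2-fold (272 and 219) and at least 4-fold (61 and 4). Single libraries carried weight in some intervals. The 11828 loci changed from 0.5 h to 1 h became 7862 without 1 h replicate 2, and the 1356 from 24 h to 48 h became between 643 and 763 without 1 of the 4 libraries compared. The 6402 from 6 h to 12 h became 2737 without 6 h replicate 1, 3338 without 12 h replicate 2 and 4164 when only the 4 libraries compared were fitted. The 5191 from 12 h to 24 h became 3425 without 12 h replicate 1, 3436 without 24 h replicate 1 and 2806 without 24 h replicate 2. The 7617 from 48 h to 96 h became 5003 without 48 h replicate 2 and 3931 without 96 h replicate 2.

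**Figure D4:**
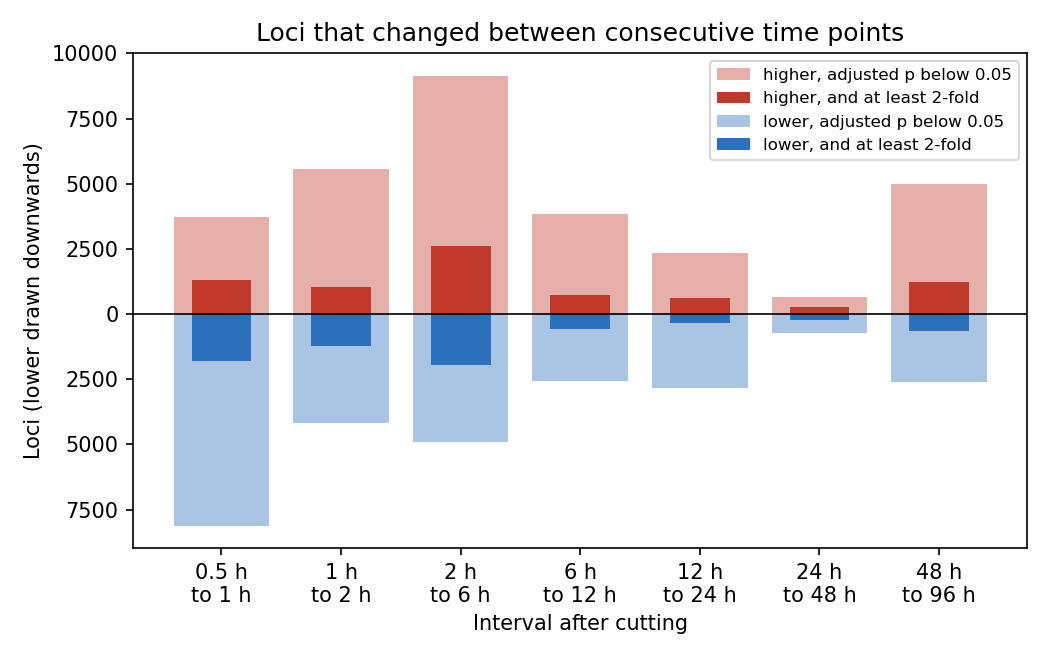
Number of loci higher (upwards) and lower (downwards) at the later of each pair of consecutive time points, with pale bars for adjusted p below 0.05 and dark bars for those also changed at least 2-fold. The tallest bar is 9155 loci higher at 6 h than at 2 h, and the shortest are 644 and 712 from 24 h to 48 h.

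Many loci moved in more than 1 interval. Of those tested, 3857 (14.4%) were called in no consecutive comparison, 6070 in 1, 6854 in 2 and 30 in all 7. Loci that rose to a time point and fell after it numbered 914 at 1 h, 1251 at 2 h, 1111 at 6 h, 349 at 12 h, 66 at 24 h and 202 at 48 h. Independent lists of the same sizes would share 577.9, 1018, 879.4, 405.9, 62.7 and 63.0 loci. Loci that fell and then rose numbered 1618, 1306, 676, 263, 50 and 209 at these time points, where independent lists would share 1690, 1426, 699.9, 226.2, 68.2 and 133. Loci that rose in both adjoining intervals numbered 1032, 2150, 1625, 627, 172 and 121, against 772.4, 1906, 1310, 337.1, 56.7 and 120.3 for independent lists. Those that fell in both numbered 1584, 1343, 619, 510, 146 and 112, against 1264, 761.7, 469.7, 272.4, 75.4 and 69.6. Unchanged groups simulated around a shared middle time point gave 0 loci that rose and then fell in 20 runs, but such groups yield almost no calls, so this value does not show how much the shared libraries add. Both comparisons use the same 2 middle libraries, which cannot be split. An error in these enters the 2 differences with opposite signs. Part of the overlaps of loci that turned, by rising and then falling or the reverse, may therefore come from them. Overlaps of loci that moved in the same direction in both intervals are lowered by such an error, not raised. Each locus has 1 estimate of its spread for all intervals, however, so loci of low spread are called more often in both. That can raise every overlap above that of independent lists, by an amount that was not tested.

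Among the 24464 loci that changed after cutting, the highest mean fell most often at 96 h (5452 loci, 22.3%), then at 0.5 h (3702) and 6 h (3460), and least often at 24 h (1417). The lowest mean fell at 1 h in 6589 loci (26.9%) and at 2 h in 5009 (20.5%). Of loci with a range of at least 4-fold, 1069 were highest at 0.5 h, 958 at 1 h, 635 at 2 h, 661 at 6 h, 284 at 12 h, 341 at 24 h, 765 at 48 h and 1283 at 96 h. Those highest at 1 h were at a median of -0.85 on the log2 scale relative to their maximum at 0.5 h, -0.96 at 2 h and -2.28 at 6 h. Those highest at 12 h were at a median of -2.32 at 1 h and -0.82 at 96 h. The time of the maximum is a description of means of 2 libraries and was not tested per locus. These times also rest on the authors' scaling and were not computed with quantile normalization. The median log2 fold change of all loci from 0.5 h to 1 h was -0.165 with the first and -0.039 with the second. From 48 h to 96 h it was 0.074 and -0.021. Part of the minima at 1 h and of the maxima at 96 h may therefore come from the scaling.

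**Figure D5:**
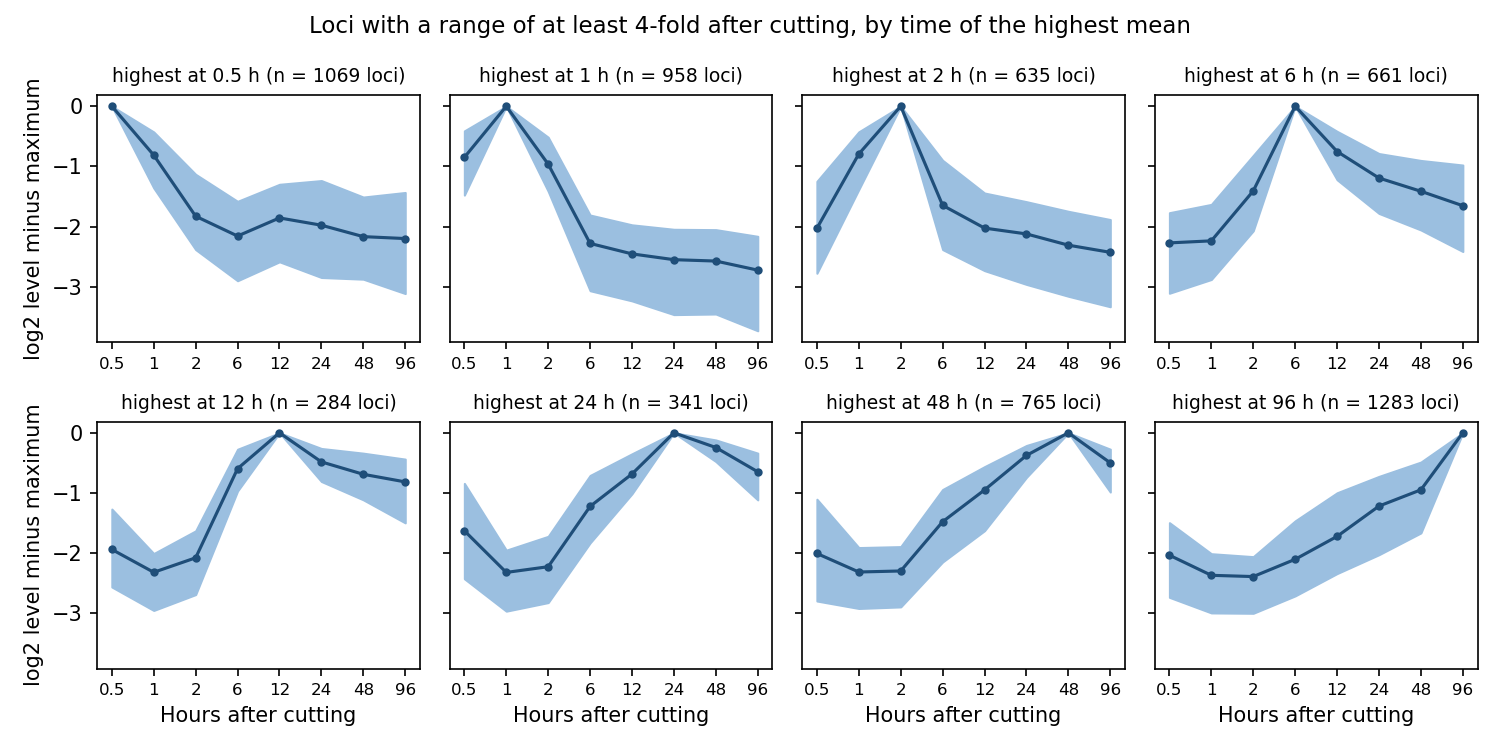
Level of loci with a range of at least 4-fold after cutting, as log2(FPKM + 1) minus the maximum of the locus, against hours after cutting with time points evenly spaced, in 8 groups by the time of the highest mean. Lines are medians and bands the quartiles over loci; the group highest at 1 h had a median of -2.28 at 6 h, and the group highest at 12 h had a median of -0.82 at 96 h.

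Between the late and the early phase, which also leaves out the 0 h levels, 13653 loci were higher late and 7275 lower, 78.2% of those tested. At least 2-fold changes were found in 3900 loci upwards and 2685 downwards, and at least 16-fold changes in 66 upwards and 150 downwards. With quantile normalization the share of higher loci was 55.1% in place of 65.2%, and the median log2 fold change of all loci was 0.072 in place of 0.233. With a minimum of 2-fold the changed loci numbered 6585. Potri.005G190100 rose by 3.74 on the log2 scale and Potri.004G168600 fell by 5.55 (limma, Benjamini-Hochberg adjusted p 2.4e-08 and 3.46e-11). The log2 fold change of Potri.003G207000 was -1.065 and that of Potri.007G026100 -0.097 (limma, Benjamini-Hochberg adjusted p 0.000118 and 0.213). All 4 loci were picked by their levels in the same 6 late libraries, so these p-values are not free of that choice.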

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

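Chosen only after seeing the data were transcripts as deposited, loci with 1 listed transcript, loci not listed at 0 at 0 h, limma-voom and fits without 0 h. The 20 counts of changed loci stayed within 1.5 times under quantile normalization, no filter on low values, a pseudocount of 0.1, limma without trend and robust estimation and limma-voom. So did the 11 counts against 0 h without loci listed at 0 in both 0 h libraries, and the 9 counts without the 0 h libraries. Totals hide turns of the prevailing direction under these settings, which the report gives. The late-phase fold changes of the 4 named loci kept their direction and passed the test under every alternative that gave them a value, but sizes moved. That of Potri.005G190100 was 9.74 and 7.87 without 0 h replicate 1 and 2. With a pseudocount of 0.1 and with limma-voom it was 9.53 and 9.70, and that of Potri.003G207000 -6.55 and -6.74. Potri.007G026100, listed at 0 at 0 h, moved most, since its fitted value depends on the pseudocount and is no bound. The gene lists gave no value under any alternative, as no identifier is paired with a name, and planned count models were not run on FPKM.

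With transcripts as deposited, 52352 were tested. Against 0 h, 39804 changed at 0.5 h, 41531 at 1 h, 41562 at 2 h, 41151 at 6 h, 40958 at 12 h, 40660 at 24 h, 41211 at 48 h and 41686 at 96 h. In the early, middle and late phase 43169, 42619 and 43380 changed. From 0.5 h to 1 h 18189 changed, from 2 h to 6 h 23059, between late and early phase 37874, and over the time course 49856. Of the tested, the share changed at 0.5 h rose from 49.7% to 76.0%, while it fell from 44.2% to 34.7% from 0.5 h to 1 h.

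Among the 14378 loci with 1 listed transcript the counts are lower, in part because fewer loci were tested. As with transcripts as deposited, higher loci prevailed at 1 h, at 2 h and in the early phase, against the reported direction. Both settings carry the transcripts listed at 0 at 0 h. Against 0 h, 7527 of the 14378 loci changed at 0.5 h, 9413 at 1 h, 9568 at 2 h and 9112 at 6 h. At 12 h 8870 changed, at 24 h 8424, at 48 h 8981 and at 96 h 9472. In the early, middle and late phase 9841, 9633 and 10006 changed, between late and early phase 10847, and over the time course 13576. Between consecutive time points, from 0.5 h on, 5426, 4475, 6756, 2891, 2286, 824 and 3775 changed. The share of tested loci that changed was lower here in 6 of the 7 consecutive intervals (37.7% in place of 44.2% from 0.5 h to 1 h) and in 5 of the 8 comparisons of a time point with 0 h, and higher in the others (52.4% in place of 49.7% at 0.5 h), for causes not tested.

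A minimum of 2-fold left 7009, 7204 and 6838 loci in the 3 phases against 0 h and 6585 between late and early phase. Fitting only the 4 libraries compared left 4164 loci from 6 h to 12 h.

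With 1 library left out, the other is assumed to vary like the rest. The counts then ranged from 7862 to 10002 for 0.5 h to 1 h (7862 without 1 h replicate 2), from 2737 to 5699 for 6 h to 12 h (2737 without 6 h replicate 1, 3338 without 12 h replicate 2), and from 2806 to 3561 for 12 h to 24 h (3425 without 12 h replicate 1, 3436 and 2806 without 24 h replicate 1 and 2). They ranged from 643 to 763 for 24 h to 48 h (718 and 643 without 24 h replicate 1 and 2, 650 and 763 without 48 h replicate 1 and 2), and from 3931 to 5329 for 48 h to 96 h (5003 without 48 h replicate 2, 3931 without 96 h replicate 2). Fewer samples are part of each drop. The other 15 counts stayed within 1.5 times.

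The replicate numbers are shared between time points without a label that ties them to a batch. Differences between replicate 1 and 2 correlated across loci between -0.20 and 0.21 over 36 pairs of time points, above 0.1 in 3, so the numbers do not pair the samples. A replicate block moved the counts by a factor between 0.951 and 0.997, for example to 1290 loci from 24 h to 48 h. In simulated data with 200 changed loci, 31.4% of loci changed 1.5-fold were recovered from 0.5 h to 1 h, which does not carry over to the measured data with far more calls.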

Other observations

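The tests on the leading transcript, on whole reads, on read depth and on splits of single libraries were chosen after related values had been seen, and the test on same-length transcripts and those on neighbouring loci and transcript lengths before. The splits of time points were added after those of single libraries had been seen, and the count over 7 intervals for whole neighbourhoods after the values of each interval.

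Loci that are neighbours in the numbering of the identifiers often moved together after cutting. Of the 1297 loci that rose at least 2-fold from 0.5 h to 1 h, 193 neighbouring pairs rose together, where 1000 random lists matched on FPKM gave a median of 59.0 and at most 82. In all 14 lists, rising or falling over the 7 intervals, the pairs exceeded the highest random list. From 2 h to 6 h, 425 rising pairs stood against at most 281, and 342 falling pairs against at most 177. Identifier numbers within 200 of each other were taken as neighbours, and the numbering is used only as an order.

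Reads shared between similar neighbouring copies may add to this pattern, since 27.98% of the rising pairs from 0.5 h to 1 h had lengths within 10% of each other, against 13.04% of all neighbours. Without such pairs 139 remained, more than the highest of the random lists (73), and the same held in 13 of the 14 lists, which argues against shared reads between copies of similar length as the whole cause. Copies of unlike length stay open, because no sequence was used here. A change of whole neighbourhoods stays open too. The neighbours compared were those outside the list, so they include loci that moved the same way by less than 2-fold. In 6 of the 7 rising lists these neighbours had a positive median log2 fold change above the highest random list (0.193 against 0.114 from 2 h to 6 h). From 0.5 h to 1 h their median was above the highest random list but negative (-0.085 against -0.155). In 6 of the 7 falling lists it was below the lowest random list. Of these, the median for 2 h to 6 h was positive all the same (0.085 against 0.175). A shared regulation of related neighbours is a hypothesis that was not tested.

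The spread of FPKM over transcripts at 0 h may come from another way of assigning reads to transcripts in those files. Whole reads, the observation that prompted this explanation, go with it: their share was 59.0 percentage points lower at 0 h than in any later library left out of the search for lengths, and within 0 h it was lower in loci with several transcripts (15.78% and 15.004%) than with 1 (83.7% and 83.4%). Lower depth at 0 h is argued against: after thinning each later library to the smaller 0 h read total, the median share of the leading transcript was at most 49.8%. A change of transcript use within 0.5 h of cutting stays open: the share of loci with 2 transcripts of similar length whose leading transcript held above 80% was at most 2.61% in any later library, against 87.0% and 86.8% at 0 h, but that measure is the pattern itself and decides nothing, a judgement made after it was run (taken as it stands, it argues against this explanation). Such a change and the difference between files cannot be told apart, because both 0 h libraries come from the files that differ in kind.

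A set of 159 loci was at least 4-fold higher at 0.5 h than at 0 h and was then called in no later interval, while 8 loci were at least 4-fold lower in that way. The median of the 159 was 0.0604 FPKM at 0 h, 7.55 at 0.5 h and 7.04 at 96 h, and 76 of them were listed at 0 in both 0 h libraries. Of the 159, 144 had 1 listed transcript, where 53.7% of all tested loci had 1. The median length of the 159 was 471 bp, against 1587 bp over all tested loci. The level of the 159 at 0.5 h predicts a median of 85.7 reads in the shallower 0 h library. So many reads would be seen at that depth. The choice of loci at least 4-fold higher in FPKM + 1 largely sets this outcome, however, so it is no separate test of lower depth. Different placement of reads from near-identical copies could not be decided: the odds ratio of having a transcript of the same length and similar level in another locus was 0.37, but 89.0% of other loci have one, which makes that test uninformative, a judgement made after it was run (taken as it stands, the ratio argues against this explanation). A fast and lasting response to cutting and a difference between the files cannot be told apart for these loci, because the files of both 0 h libraries differ in kind from all others.

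Loci that changed at least 2-fold tended to have shorter transcripts than 1000 random lists matched on FPKM, in 11 of 14 lists over the 7 intervals, with a median of 1097 bp for loci that rose from 24 h to 48 h against 1520 bp in matched lists and 1456 bp against 1587 bp for loci that rose from 0.5 h to 1 h (permutation, adjusted p by Benjamini-Hochberg 0.00311 each, with a raw p of 0.002, the smallest these lists can give). Loci that fell from 0.5 h to 1 h, with 1625 bp against 1649 bp, did not pass (permutation, adjusted p 0.296). Against lists matched on reads, 13 of the 14 lists had a shorter median than every random list, including those that fell from 0.5 h to 1 h (1625 bp against 1690 bp), and loci that rose from 48 h to 96 h had a longer one (1454 bp against 1352 bp). No random list was matched on FPKM and reads at once. At equal FPKM a shorter locus has fewer reads and so more counting error. At equal reads it has a higher FPKM, whose change log2(FPKM + 1) understates less. Either can bring shorter loci past the 2-fold minimum more often. The random lists were also not matched on the number of listed transcripts. Of the loci that rose from 24 h to 48 h, 78.07% had 1, against 53.72% of all tested loci. The share was below 53.72% only for loci falling from 0.5 h to 1 h (52.49%) and rising from 2 h to 6 h (51.77%). Length apart from the number of transcripts was not tested. Loci were drawn singly although neighbours often moved together, so these p-values treat loci as independent.

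Of 100 splits of the 12 early and late libraries into groups of 6, only 1, the real one, gave as many changed loci, 15524 in a limma fit of 2 groups, and the highest other split gave 7618. These splits mix single libraries and break up the 2 similar libraries of a time point, so they exclude chance for single libraries only and say nothing of time points grouped by chance. With the libraries of a time point kept together there are 10 splits, of which 1, the real one, gave 15524 loci and the highest other 394, and these are too few for a share under 0.05.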
